A study of Homo sapiens with 30 samples.

How the data were processed

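Gene expression was measured by mRNA sequencing of 30 libraries from HT29 cells. Per the labels, libraries were made from 1 µg of total RNA (integrity number above 7) with a directional MGI kit and sequenced as paired 100 bp reads. The deposited table holds expected counts per gene, made by the authors with RSEM. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 and the build GRCh38, also written hg38. The annotation release and the strand setting are not given in the sources used here, so values of antisense genes such as IGFL2-AS1 and CYP1B1-AS1 rest on an unknown setting. The table has 60675 genes and 270 columns, of which 30 belong to these samples and 240 were not used here. Of the values above 0, 25.48% were not whole, and all were rounded, by at most 0.5.

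Samples were grouped by the extract and dose in the labels. The label of the control gives 0.1% DMSO, whereas the series text gives 2% DMSO, and the label was followed. The series text also describes hot water extracts and wortmannin, which were not analysed here, and says that samples with too little RNA were left out. It adds that extracts with a 20% inhibitory concentration under 500 µg/mL were given at that concentration and its dilutions, but the labels of all extracts here give 500, 100 and 20 µg/mL. Sample codes put Banhasasim and Yijung in 1 series, Bojungikgi and Sayeok in another and the vehicle under a code of its own, so code series and group cannot be told apart for the vehicle. The titles name batch E for all 30 libraries.

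Symbols were found for 56558 gene IDs (93.21%, holding 99.86% of counts), and GRCh38 coordinates were taken from GENCODE release 29, which held 57055 of the IDs. Genes were filtered with filterByExpr (minimum count 10), which left 18783. Counts were normalised by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with 1 mean per group over all 30 libraries, robust quasi-likelihood dispersions, 17 residual degrees of freedom, a common dispersion of 0.00407 (a biological coefficient of variation of 6.38%) and a median prior of 7.89 degrees of freedom. The low dispersion means that small fold changes were called. Each of 15 comparisons was a two-sided quasi-likelihood test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The change from 20 to 500 µg/mL was compared between Banhasasim and Bojungikgi and between Banhasasim and Sayeok by interaction terms. Log2 fold changes are given with an approximate standard error (SE). It is the absolute log2 fold change divided by the square root of the F statistic of its test. Group means in CPM are given with the SD over libraries.

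The samples, comparisons, tests, named-gene rule, gene lists and first set of alternatives were fixed before the data were examined. The genes named are the 10 higher and 10 lower with the largest absolute log2 fold change for 500 µg/mL against the vehicle, and 5 and 5 for the other comparisons. They had to be called, have a proper symbol, reach a mean of 5 CPM in 1 of the groups and show no overlap between libraries of the groups. For a list, the 4 members with the smallest p and a mean of at least 1 CPM in 1 group could be named, and a gene named for a list in 1 comparison could be given again in another. For Yijung, 5 higher and 5 lower genes per dose were picked by log2 ratio (pseudocount 0.05 CPM, at least 10 CPM, outside the range of the vehicle libraries). Mitochondrial genes outside this rule, ND5 and ND6, were chosen after their values were seen. Some genes that met the rule are not reported, mostly members of lists.

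The 28 lists held 491 genes, of which 454 were measured, and came from textbook knowledge. NQO1 was on both the AhR and the NRF2 list, ABCC2 on both the NRF2 and the PXR and CAR list, and FABP1 on both the PPAR and the colonocyte list. They were targets of AhR, NRF2, PXR and CAR, ATF4, PPAR, p53, Wnt, YAP, NF-kB, interferon and MAPK signalling; the unfolded protein and heat shock responses; cholesterol and fatty acid synthesis; metallothioneins; hypoxia and glycolysis; mitochondrially encoded mRNAs and nuclear oxidative phosphorylation; autophagy and lysosome; G2/M and G1/S genes; colonocyte and goblet cell genes; tight junctions; cytosolic ribosomal proteins; and markers of fibroblasts and endothelium and of leukocytes. Each was tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members were also counted when adjusted over the list alone. Yijung lists were ranked among 10000 random lists of like expression.

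Pairing was checked because libraries share replicate numbers, which are in the sample titles and codes. The profiles of same-number libraries, less their group means, correlated above 0.1 in every pair for Bojungikgi against Sayeok at 20 µg/mL (0.16 to 0.378), Sayeok 100 µg/mL against vehicle (0.121 to 0.553) and Sayeok 20 µg/mL against vehicle (0.117 to 0.277). With replicate as a block these called 0, 2917 and 3778 genes. In the other comparisons at least 1 pair was lower, as in Bojungikgi 500 µg/mL against vehicle (-0.528 to 0.628), so the number is not treated as a pairing.

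The test was checked on simulated data with 200 changed genes per comparison, 50 at each fold, planted among genes with a mean of at least 1 CPM. Simulated libraries were independent draws without departing libraries. Between 38% and 70% of 1.25-fold, 78% and 94% of 1.5-fold, 94% and 100% of 2-fold and 96% and 100% of 4-fold changes were recovered. Where 18418 to 18475 genes were tested, changed ones included, 2 to 12 genes without a change were called. To judge fold changes that share the vehicle, 20 sets of counts without a treatment effect were simulated. Library totals of 36.274 to 71.626 (in units of 1e6 counts) give floors of 0.0419 to 0.0827 CPM for 3 counts.

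The alternatives fixed beforehand were relative log expression size factors, no filter on low counts, a replicate block, DESeq2 1.42.0, only the compared groups in the fit, each library left out in turn, the other list tests, and for Yijung an edgeR fit that pools the spread of the other groups. A correction for GC content and transcript length (natural splines, known for 18642 genes or 99.25% of those tested), the same with a replicate block, and a fit without vehicle replicate 1 and Bojungikgi 500 µg/mL replicate 2 were chosen after seeing the data. Interaction terms could not be fitted with only 2 groups.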

Results

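Messenger RNA was sequenced from HT29 cells, an established human colorectal adenocarcinoma line. The cells had spent 24 h with a 70% ethanol extract of Bojungikgi, Sayeok, Banhasasim or Yijung, or with solvent alone. These are Korean herbal formulas prescribed for digestive complaints. The series was set up to turn the response of cells to such medicines into transcriptome data. The 30 libraries fell into 13 groups. There were 3 vehicle libraries and 3 at each of 500, 100 and 20 µg/mL for Bojungikgi and for Sayeok. There were 2 at each dose for Banhasasim (replicates 2 and 3) and 1 at each dose for Yijung (replicate 3). Total expected counts, in units of 1e6, ranged from 36.274 (Sayeok 500 µg/mL replicate 3) to 71.626 (vehicle replicate 2), with a median of 50.054. A floor of 3 counts corresponded to between 0.0419 and 0.0827 CPM (counts per 1e6 counts), and such floors cover counting error only. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

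On the first principal component, which held 12.19% of the variance, vehicle replicate 1 lay at -57.26, away from the other vehicle libraries at -18.45 and -11.22. Bojungikgi 500 µg/mL replicate 2 lay at the opposite end, at 32.36. These libraries also held the highest and the lowest share of counts on ribosomal protein genes, 6.91% and 3.775%. The Banhasasim 500 µg/mL libraries stood apart on the second component (7.18% of the variance), at 33.1 and 30.89. On the first they lay apart, replicate 2 at -28.73 and replicate 3 at -2.27, and their chi-square per gene (45.073) was the highest of any pair of replicates. Because every comparison with the vehicle rests on the 3 vehicle libraries, changes between doses of the same extract, whose fold changes do not use them, are given first. The vehicle libraries still enter the dispersions behind those calls.

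**Figure D1:**
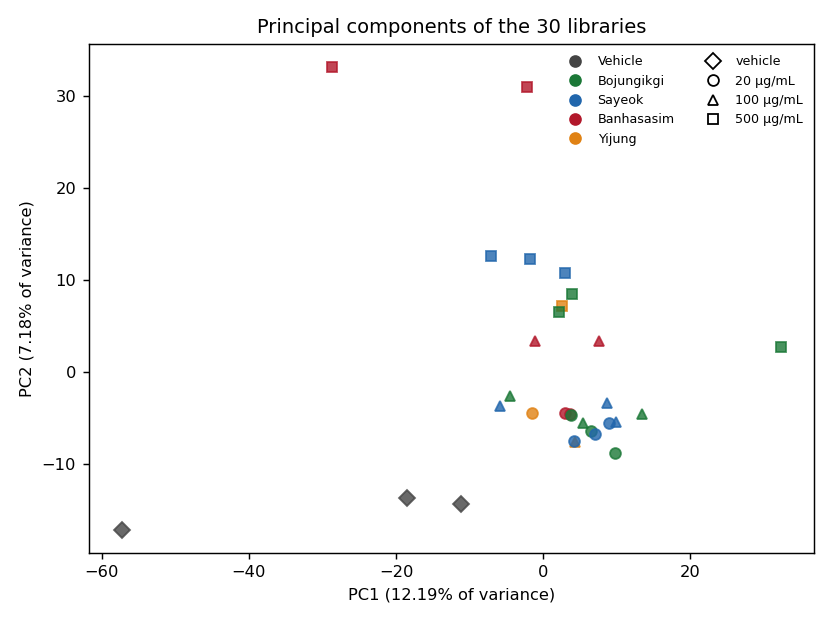
Principal components 1 (12.19% of the variance) and 2 (7.18%) of log2 CPM, where each point is a library and the colour gives its group. Vehicle replicate 1 lies at -57.26 on component 1, and both Banhasasim 500 µg/mL libraries lie above 30 on component 2.

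The comparison of Banhasasim at 500 and 20 µg/mL (n = 2 each) asked what the extract changed with dose. CYP1A1, which encodes the cytochrome P450 that the aryl hydrocarbon receptor (AhR) induces when it binds plant or pollutant aromatics, rose from 1.39 ± 0.264 (SD) to 94.8 ± 7.35 CPM. Its log2 fold change was 6.12 ± 0.17 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.16e-18). CYP1B1, another oxidase under the same receptor, rose from 100.0 ± 2.43 to 361 ± 15.0 CPM, by 1.85 ± 0.05 (adjusted p = 1.16e-18). ASNS, the asparagine synthetase that ATF4 induces when amino acids run short, rose from 66.9 ± 0.318 to 244 ± 5.98 CPM, by 1.87 ± 0.05 (adjusted p = 9.72e-19). CHAC1, an ATF4 target that degrades glutathione, rose by 2.77 ± 0.11 (adjusted p = 7.13e-16). SLC6A9, a glycine transporter, rose by 3.15 ± 0.17 (adjusted p = 8.73e-13). The 5 largest rises also held the mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2. TXNIP, a glucose-responsive inhibitor of thioredoxin, changed by -1.28 ± 0.06 (adjusted p = 3.18e-14). NOX1, the superoxide-producing oxidase of colon epithelium, changed by -1.25 ± 0.09 (adjusted p = 2.77e-10). The other largest falls, of MT-ND4, MT-ND4L and MT-CO3, were called only with all groups in the fit. CYP1A1 (ENSG00000140465) lies on chromosome 15 at 74719542 to 74725610 and CYP1B1 (ENSG00000138061) on chromosome 2 at 38066973 to 38109902. ASNS (ENSG00000070669) lies on chromosome 7 at 97852118 to 97872542 and CHAC1 (ENSG00000128965) on chromosome 15 at 40952962 to 40956519 (GRCh38).

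In all, 1468 of 18783 genes were called between these doses, 717 higher and 751 lower at 500 µg/mL, and 170 changed more than 2-fold. The count was 636 without Banhasasim 500 replicate 2, 777 without Banhasasim 20 replicate 2 and 749 without Banhasasim 20 replicate 3. In simulations with planted changes this comparison recovered 84% of 1.5-fold changes and 38% of the smallest changes planted, so small differences were often missed.

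The lists of AhR, NRF2 and ATF4 targets and of MAPK output genes rose with the Banhasasim dose. Of 8 AhR targets measured, 7 were higher and 0 lower, the same numbers when adjusted over the list alone (camera adjusted p = 1.8e-22). They included the aldehyde dehydrogenases ALDH1A3 (1.38 ± 0.07) and ALDH3A1 (1.58 ± 0.09). Of 24 targets of NRF2, the regulator of antioxidant and conjugating enzymes, 20 were higher and 0 lower (21 and 0 adjusted over the list alone, camera adjusted p = 6.23e-33). Among them AKR1C2, an aldo-keto reductase that reads of its paralog AKR1C1 could reach, rose by 1.5 ± 0.10, the cystine transporter SLC7A11 by 1.21 ± 0.09 and the haem oxygenase HMOX1 by 0.87 ± 0.08. Of 22 ATF4 targets, 21 were higher and 0 lower, as when adjusted over the list alone (camera adjusted p = 7.23e-49). Among them were the serine synthesis enzyme PSAT1 (1.42 ± 0.06), the mTORC1 inhibitor DDIT4 (2.09 ± 0.09) and the pseudokinase TRIB3 (1.13 ± 0.08). Of 17 MAPK output genes, 7 were higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 6.86e-04). The immediate early genes IER3 and EGR1 rose by 0.70 ± 0.11 and 0.46 ± 0.08. These 4 calls held with an estimated correlation (adjusted p between 1.04e-07 and 0.0178).

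Sterol and interferon genes fell over the same doses. Of 24 cholesterol synthesis genes, 0 were higher and 13 lower (0 and 18 adjusted over the list alone, camera adjusted p = 4.12e-13 and adjusted p = 9.41e-04 with an estimated correlation). HMGCS1, which makes the HMG-CoA that statin-sensitive reductase consumes (ENSG00000112972, chromosome 5 at 43289395 to 43313512), changed by -0.55 ± 0.06. The sterol sensor INSIG1 changed by -0.41 ± 0.05. Of 20 interferon response genes, 0 were higher and 12 lower (0 and 13 adjusted over the list alone, camera adjusted p = 5.78e-10 and adjusted p = 0.019 with an estimated correlation). IFIT1, which binds viral RNA caps, changed by -0.87 ± 0.14 and the interferon signal transducer IRF9 by -0.64 ± 0.10.

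A further 10 lists were called by camera with the preset correlation but not with an estimated one. The goblet cell and mucin list was lower (16 genes, 0 higher and 5 lower, 0 and 6 adjusted over the list alone, camera adjusted p = 0.0147, adjusted p = 0.0659 with an estimated correlation). So were Wnt targets and stem cell genes (14 genes, 0 and 3, 1 and 5 adjusted over the list alone, camera adjusted p = 0.0189, then 0.199). Fatty acid synthesis (11 genes) had 0 higher and 1 lower, as when adjusted over the list alone (camera adjusted p = 0.0189, then 0.264). Tight and adherens junctions (18 genes) had 1 and 3, as when adjusted over the list alone (camera adjusted p = 0.0498, then 0.0865). MUC13, a membrane mucin of the gut surface, changed by -0.57 ± 0.05 and ATOH1, the secretory lineage factor, by -0.82 ± 0.14. EPHB3, which positions crypt cells, changed by -0.70 ± 0.07 and the pore-forming claudin CLDN2 by -0.40 ± 0.06. Hypoxia and glycolysis genes were higher (19 genes, 2 higher and 0 lower, as when adjusted over the list alone, camera adjusted p = 0.00569, adjusted p = 0.0868 with an estimated correlation). So was the endoplasmic reticulum unfolded protein response (18 genes, 2 and 0, 4 and 0 adjusted over the list alone, camera adjusted p = 0.027, then 0.0607). NF-kB and inflammatory cytokines (17 genes) had 3 and 0 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0368, then 0.0659). The heat shock response (15 genes) had 1 and 0, as when adjusted over the list alone (camera adjusted p = 0.0498, then 0.312). VEGFA, the angiogenic factor, rose by 0.65 ± 0.05 and the glucose transporter SLC2A1 by 0.35 ± 0.05. Nuclear oxidative phosphorylation was higher as a list of 23 genes (camera adjusted p = 0.0498, then 0.639), and so were 28 cytosolic ribosomal proteins (camera adjusted p = 0.00261, then 0.618). In both, edgeR called 0 genes over all genes or adjusted over the list alone. Counting every list, camera called 17 in this comparison with the preset correlation, and 11 after the GC and length correction.

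The remaining lists were not called between 500 and 20 µg/mL of Banhasasim, though single members were. For PXR and CAR drug metabolism, 2 of 9 genes were higher and 0 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.565). The numbers were 3 and 2 of 14 PPAR targets and fatty acid oxidation genes (4 and 2 adjusted over the list alone, camera adjusted p = 0.394). They were 2 and 1 of 20 autophagy and lysosome genes (3 and 1 adjusted over the list alone, camera adjusted p = 0.664). Among 23 G1/S and DNA replication genes 1 was higher, also adjusted over the list alone (camera adjusted p = 0.269). Among 18 p53 targets 2 were higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.698). Colonocyte and enterocyte differentiation had 3 and 3 of 17 (6 and 4 adjusted over the list alone, camera adjusted p = 0.952). YAP targets had 1 and 1 of 12 (2 and 2 adjusted over the list alone, camera adjusted p = 0.277). SESN1, a p53 target that restrains mTORC1, changed by -0.59 ± 0.07 and the glucose transporter SLC5A1 by -0.68 ± 0.07. No member was called among 6 metallothionein and zinc export genes (camera adjusted p = 0.934), 22 G2/M and mitosis genes (0.984), 4 fibroblast and endothelial markers (0.975) and 5 leukocyte markers (0.628). The signs of median and mean differed for PXR and CAR (-0.009 and 0.023), p53 targets (0.019 and -0.048), G2/M (0.003 and -0.011) and fibroblast and endothelial markers (0.047 and -0.131). For metallothioneins the median was -0.023 and the test pointed upward.

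**Figure D2:**
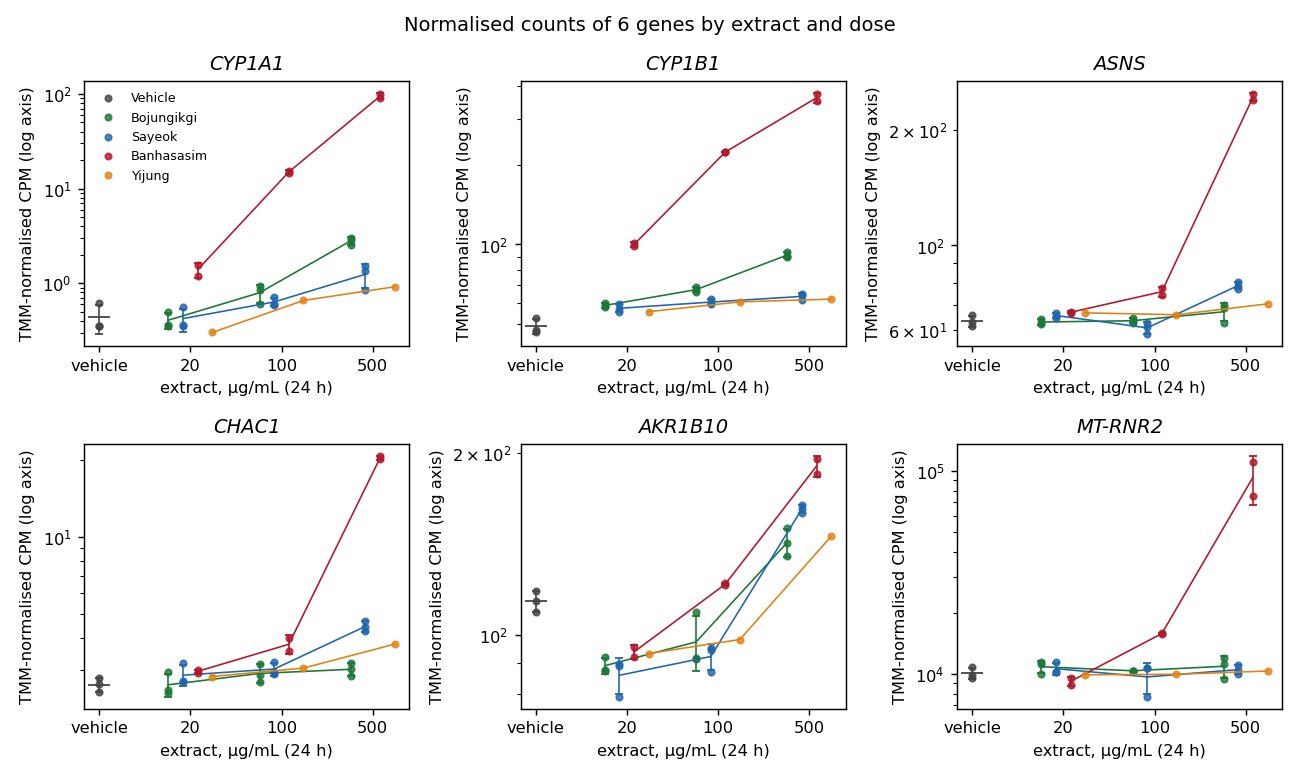
CPM (log axis) against dose in µg/mL, with the vehicle, for CYP1A1, CYP1B1, ASNS, CHAC1, AKR1B10 and MT-RNR2, where points are libraries, lines join group means and bars are the SD of groups with n above 1. CYP1A1 reached 94.8 CPM at 500 µg/mL of Banhasasim against 2.81 for Bojungikgi and 1.24 for Sayeok, and AKR1B10 was highest at 500 µg/mL of Banhasasim, Bojungikgi and Sayeok alike.

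Mitochondrial ribosomal RNAs rose with the Banhasasim dose, while some mitochondrial mRNAs were lower. MT-RNR1 (ENSG00000211459, chromosome M at 648 to 1601), the small ribosomal RNA of the mitochondrion, rose by 4.57 ± 0.17 (adjusted p = 6.07e-14). MT-RNR2 (ENSG00000210082, 1671 to 3229), the large one, rose by 3.35 ± 0.16 (adjusted p = 3.22e-12). Together they took 12.862% and 9.408% of counts in the 500 µg/mL libraries, 1.901% and 1.914% at 100 µg/mL, and between 0.914% and 1.383% in every other library of the study. Of 13 mitochondrially encoded mRNAs, 0 were higher and 5 lower (1 and 8 adjusted over the list alone, camera adjusted p = 3.2e-08 but adjusted p = 0.142 with an estimated correlation). Their median change was -0.94. MT-ND4, a complex I subunit, changed by -1.50 (adjusted p = 5.2e-05), and MT-CO1, the catalytic subunit of cytochrome oxidase, by -1.09 ± 0.15 (adjusted p = 3.25e-05), and neither was called with only these groups in the fit. ND5, by contrast, changed by -0.08 (adjusted p = 0.874) and ND6, alone on the other strand, by 0.84 (adjusted p = 0.189). The share of these mRNAs at 500 µg/mL was 3.993% and 2.556% of counts, against 5.147% to 8.26% in the other libraries.

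**Figure D3:**
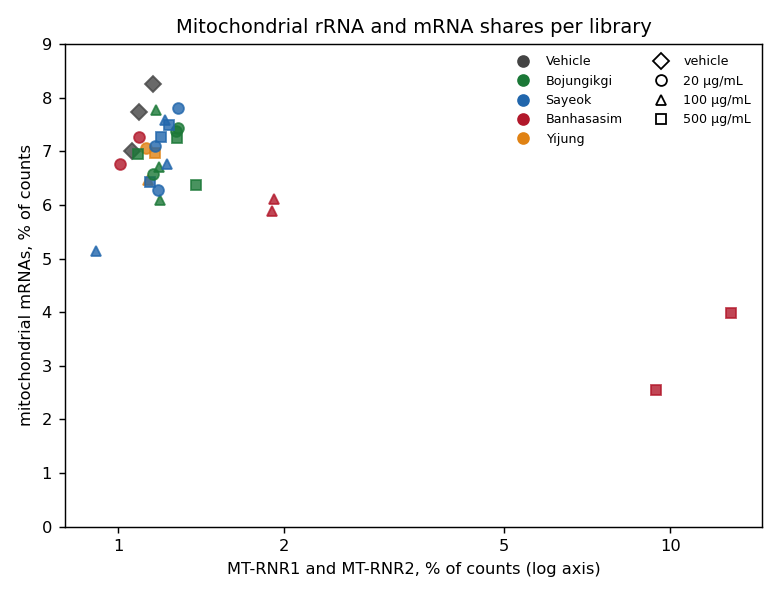
Share of counts on MT-RNR1 and MT-RNR2 (percent, log axis) against the share on mitochondrially encoded mRNAs (percent), where each point is a library and the colour gives its group. The Banhasasim 500 µg/mL libraries hold 12.862% and 9.408% ribosomal RNA with 3.993% and 2.556% mRNA, and no other library exceeds 1.914% ribosomal RNA.

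The same comparison for Sayeok (500 against 20 µg/mL, n = 3 each) had aldo-keto reductase genes among its largest rises. AKR1C2 (ENSG00000151632, chromosome 10 at 4987400 to 5018031) rose from 7.54 ± 0.458 to 22.3 ± 0.606 CPM, by 1.57 ± 0.09 (edgeR adjusted p = 8.81e-12). AKR1B10, which reduces retinal and lipid aldehydes, rose from 85.9 ± 5.84 to 162 ± 2.43 CPM, by 0.91 ± 0.06 (adjusted p = 4.58e-10). ALDH3A1 rose by 1.05 ± 0.07 (adjusted p = 4.76e-10) and AKR1C1 by 0.96 ± 0.08 (adjusted p = 3.97e-08). The rise of AKR1C3 (0.85 ± 0.16) was called only with all groups in the fit. The urea transporter SLC14A1 changed by -1.20 ± 0.09 (adjusted p = 2.46e-09), and the long non-coding RNA LINC00261 by -0.81 ± 0.07 (adjusted p = 1.19e-08). The amino acid transporter SLC6A20 changed by -0.72 ± 0.06 and the antiviral genes OAS2 and MX1 by -0.98 ± 0.16 and -0.71 ± 0.12. The test called 597 genes, 215 higher and 382 lower, 36 of them more than 2-fold. It called 386 without Sayeok 500 replicate 1 and 386 without Sayeok 500 replicate 2.

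Among the Sayeok lists, 19 of 24 NRF2 targets were higher and 0 lower (22 and 0 adjusted over the list alone, camera adjusted p = 2.12e-41). GCLM, which limits glutathione synthesis, rose by 0.55 ± 0.05. AhR targets rose as a list with 5 of 8 higher (6 and 0 adjusted over the list alone, camera adjusted p = 8.53e-12). CYP1A1, however, rose from 0.423 ± 0.114 to only 1.24 ± 0.351 CPM (1.56 ± 0.25, adjusted p = 2.62e-04). CYP1B1 stood at 57.25 ± 1.984 CPM at 20 µg/mL and 63.5 ± 1.85 CPM at 500 µg/mL. ATF4 targets (8 higher and 0 lower, 15 and 0 adjusted over the list alone, camera adjusted p = 5.77e-14) rose through CHAC1 (0.63 ± 0.09), DDIT4 (0.43 ± 0.08) and ASNS (0.26 ± 0.04). Hypoxia and glycolysis genes (6 and 0, 13 and 0 adjusted over the list alone, camera adjusted p = 3.66e-11) rose through NDRG1, a growth arrest gene induced by low oxygen (0.80 ± 0.14). Interferon response genes fell (0 and 11 of 20, 0 and 13 adjusted over the list alone, camera adjusted p = 1.37e-13). So did cholesterol synthesis (0 and 3, 0 and 4 adjusted over the list alone, 1.12e-05) and goblet cell genes (0 and 3, 0 and 5 adjusted over the list alone, 0.00201). MUC13 changed by -0.37 ± 0.04 and REG4, a regenerating lectin of mucin-secreting cells, by -0.58 ± 0.09. G2/M genes were higher (2 and 0, 5 and 0 adjusted over the list alone, 2.12e-06), with CDC20, the activator of anaphase, up by 0.24 ± 0.05.

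Further Sayeok lists were called on few members. Higher were PXR and CAR drug metabolism (3 higher and 0 lower, 5 and 1 adjusted over the list alone, camera adjusted p = 6.96e-04) and the unfolded protein response (0 and 0, 5 and 0 adjusted over the list alone, 1.72e-04). Heat shock (1 and 0, 3 and 0 adjusted over the list alone, 1.9e-06) and PPAR targets (4 and 0, also adjusted over the list alone, 0.00201) were higher too. So were G1/S genes (1 and 0, 5 and 0 adjusted over the list alone, 1.81e-05) and NF-kB genes (2 and 0, 3 and 0 adjusted over the list alone, 0.00659). Tight junctions (0 and 1, 0 and 2 adjusted over the list alone, 0.0242) and YAP targets (0 and 1, 0 and 2 adjusted over the list alone, 0.0039) were lower. Every Sayeok list named so far was also called with an estimated correlation, and nuclear oxidative phosphorylation was not (0 and 0, camera adjusted p = 0.00659, adjusted p = 0.498 with an estimated correlation). After a correction for GC content and transcript length, tight junctions (camera adjusted p = 0.0808) and YAP targets (0.124) were no longer called. Mitochondrially encoded mRNAs were not called (0 and 0 of 13, camera adjusted p = 0.548).

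For Bojungikgi (500 against 20 µg/mL, n = 3 each) the test called 331 genes, 113 higher and 218 lower, 14 more than 2-fold. ALDH3A1 rose from 18.8 ± 0.969 to 33.3 ± 2.55 CPM, by 0.83 ± 0.07 (edgeR adjusted p = 4.98e-08). AKR1B10 rose from 89.1 ± 2.65 to 142 ± 7.53 CPM, by 0.68 ± 0.06 (adjusted p = 8.92e-08), and CYP1B1 from 58.7 ± 1.15 to 91.2 ± 2.19 CPM, by 0.64 ± 0.04 (adjusted p = 1.18e-09). The amino acid transporter SLC38A4 rose by 0.85 ± 0.11 and AKR1C2 by 0.73 ± 0.08. ACSS2, which makes acetyl-CoA from acetate under sterol control, changed by -0.74 ± 0.05 (adjusted p = 1.57e-10). IFIT1 changed by -0.86 ± 0.11, OAS2 by -0.97 ± 0.15, SLC14A1 by -0.78 ± 0.09 and the antisense RNA IGFL2-AS1 by -0.79 ± 0.10. The count was 164 without Bojungikgi 20 replicate 2 and 171 without Bojungikgi 20 replicate 3.

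AhR targets rose over the Bojungikgi doses (7 of 8 higher, 7 and 0 adjusted over the list alone, camera adjusted p = 6.71e-22), with CYP1A1 up from 0.407 to 2.81 ± 0.251 CPM (2.75 ± 0.20, adjusted p = 3.07e-09). NRF2 targets rose as well (12 and 0, 18 and 0 adjusted over the list alone, 2.16e-22). Cholesterol synthesis fell (0 and 8, 0 and 17 adjusted over the list alone, camera adjusted p = 9.5e-18), with HMGCS1 at -0.30 ± 0.04. Interferon response genes fell (0 and 10, 0 and 14 adjusted over the list alone, 2.16e-22), with IFIH1, a sensor of viral RNA, at -0.40 ± 0.06. Goblet cell genes fell too (0 and 3, also adjusted over the list alone, 2.83e-04). PXR and CAR genes (2 and 0, 3 and 0 adjusted over the list alone, camera adjusted p = 0.00917) and PPAR targets (2 and 0, 5 and 1 adjusted over the list alone, 0.0087) were higher. So were the unfolded protein response (0 and 0, 6 and 0 adjusted over the list alone, 0.00256) and heat shock (3 and 0, 4 and 0 adjusted over the list alone, 2.01e-06). Hypoxia and glycolysis (2 and 0, 3 and 0 adjusted over the list alone, 7.68e-04), G2/M (1 and 0, 3 and 0 adjusted over the list alone, 3.76e-05) and G1/S (1 and 0, 6 and 0 adjusted over the list alone, 7.46e-06) were also higher. All of these were called with an estimated correlation. ATF4 targets were not called (1 and 0, 2 and 1 adjusted over the list alone, camera adjusted p = 0.106). Autophagy and lysosome genes were lower (0 and 0, 0 and 1 adjusted over the list alone, camera adjusted p = 0.0201, adjusted p = 0.0913 with an estimated correlation). So were oxidative phosphorylation (0 and 0, 0.00903, then 0.506) and ribosomal proteins (0 and 0, 1.81e-04, then 0.501). These 3 calls were also lost with the GC and length correction.

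**Figure D4:**
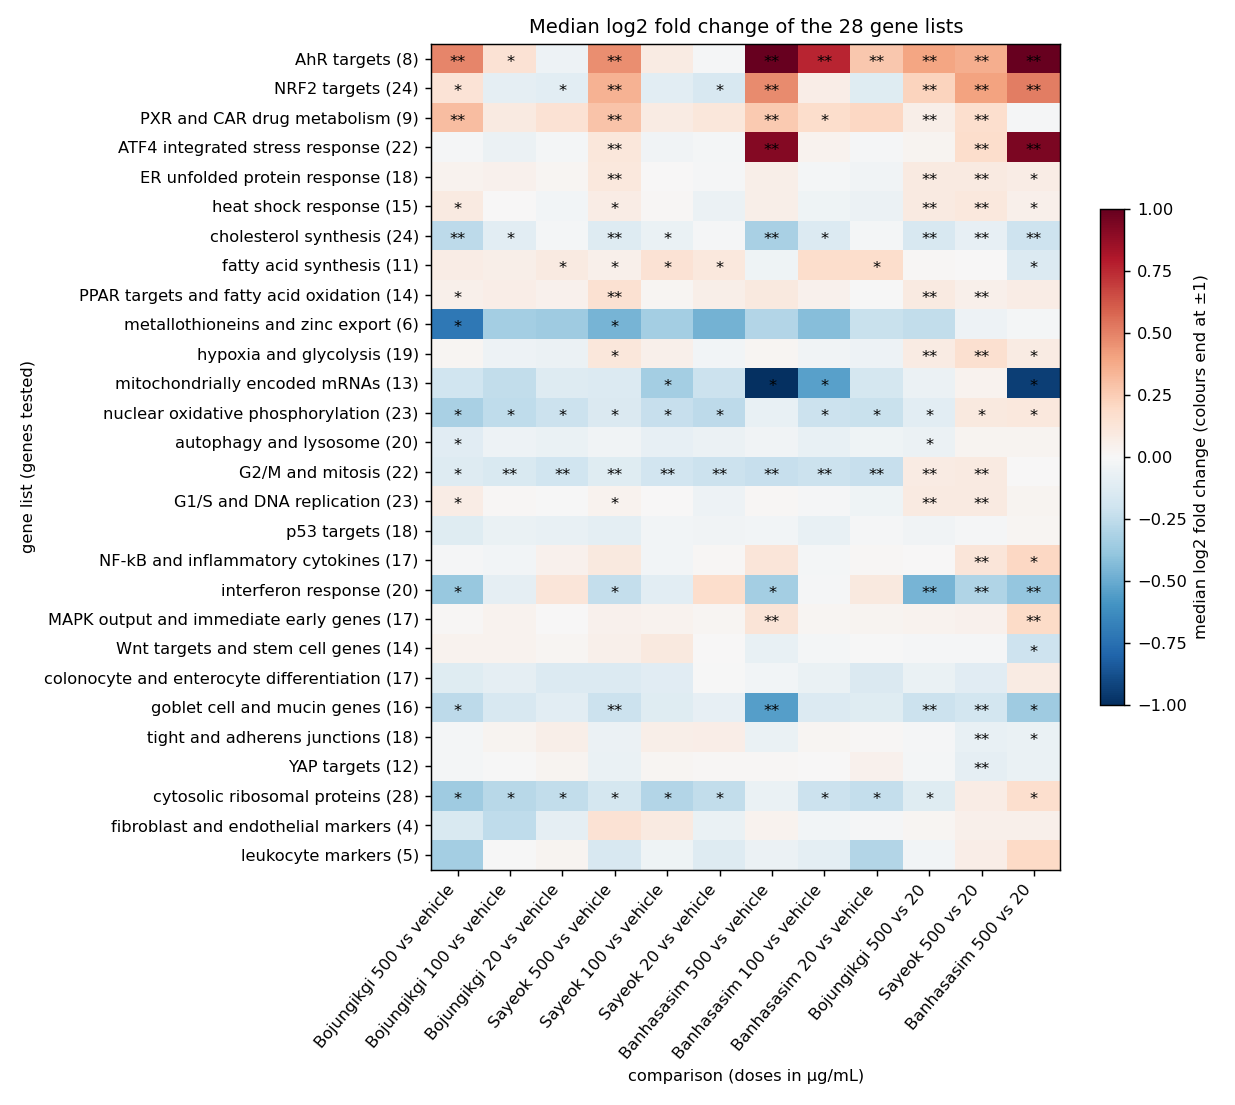
Median log2 fold change of each of the 28 gene lists (vertical) in 12 comparisons (horizontal), with colours ending at -1 and 1, where 1 star marks a camera adjusted p under 0.05 and 2 stars a call that also held with an estimated correlation. AhR targets rose most in Banhasasim 500 µg/mL against the vehicle (median 1.462), NRF2 and ATF4 targets rose most in Banhasasim 500 against 20 µg/mL (0.511 and 0.938), and G2/M genes were lower against the vehicle at 20 µg/mL of Banhasasim, Sayeok and Bojungikgi.

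Changes between 500 and 20 µg/mL overlapped between extracts, and these comparisons share no library. Of the genes called for both Sayeok and Banhasasim, 116 were higher and 233 lower in both (8.2 and 15.3 for independent lists) and 8 went opposite ways. Bojungikgi shared 58 higher and 117 lower genes with Sayeok (1.3 and 4.4 for independent lists, 0 opposite) and 64 and 123 with Banhasasim (4.3 and 8.7, 3 opposite). The figures for independent lists take every gene as equally likely to be called. All comparisons share the dispersions of 1 fit, so these figures may be too low. Across 12173 genes, which are not independent replicates, the log2 fold changes of the 3 pairs correlated with r = 0.448 (Bojungikgi and Sayeok), 0.226 (Bojungikgi and Banhasasim) and 0.537 (Sayeok and Banhasasim), with covariances of 0.0076, 0.0062 and 0.0162. Spearman's rho for the same pairs was 0.317, 0.092 and 0.519, so by rank Bojungikgi and Banhasasim agreed little.

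Interaction terms asked where the change from 20 to 500 µg/mL differed between extracts. ATF4 targets rose more with Banhasasim than with Bojungikgi (20 of 22 higher and 0 lower, 21 and 0 adjusted over the list alone, camera adjusted p = 5.47e-53) or Sayeok (17 and 0, 19 and 0 adjusted over the list alone, 1.27e-55), with median differences of 0.93 and 0.742. AhR targets also rose more, against Bojungikgi (6 and 0, 7 and 0 adjusted over the list alone, 5.3e-14) and against Sayeok (5 and 0, 6 and 0 adjusted over the list alone, 2.36e-18). For NRF2 targets the numbers were 9 and 0 against Bojungikgi (17 and 0 adjusted over the list alone, 8.15e-15) and 1 and 0 against Sayeok (4 and 0 adjusted over the list alone, 4.08e-05). Mitochondrially encoded mRNAs fell more against Bojungikgi (0 and 4, 0 and 8 adjusted over the list alone, camera adjusted p = 2.98e-07, adjusted p = 0.281 with an estimated correlation). The interferon list did not differ (camera adjusted p = 0.87 and 0.174). Over all genes, 386 differed between Banhasasim and Bojungikgi (246 rising more and 140 less) and 196 between Banhasasim and Sayeok (140 and 56). Without Banhasasim 500 replicate 2, Banhasasim 20 replicate 2 or Banhasasim 20 replicate 3 these counts were 169, 199 and 186 for the former and 130, 125 and 116 for the latter.

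Against the vehicle (n = 3), Banhasasim raised AhR targets at every dose. CYP1B1, at 48.9 ± 3.22 CPM in the vehicle, rose by 1.03 ± 0.05 at 20 µg/mL (100.0 ± 2.43 CPM, edgeR adjusted p = 3.32e-13). It rose by 2.20 ± 0.05 at 100 µg/mL (224 ± 0.683 CPM, adjusted p = 3.24e-21) and by 2.88 ± 0.05 at 500 µg/mL (361 ± 15.0 CPM, adjusted p = 5.15e-24). CYP1A1, at 0.441 ± 0.150 CPM in the vehicle, rose by 5.14 ± 0.18 at 100 µg/mL (15.0 ± 0.733 CPM, adjusted p = 2.07e-16) and by 7.81 ± 0.17 at 500 µg/mL (adjusted p = 2.22e-21). Its rise of 1.69 ± 0.25 at 20 µg/mL (adjusted p = 2.81e-04) was called only with all groups in the fit. The AhR list had 4, 6 and 7 of 8 genes higher at 20, 100 and 500 µg/mL and 0 lower (4, 7 and 7 adjusted over the list alone, camera adjusted p = 3.61e-05, 4.01e-16 and 7.6e-22). TIPARP, an AhR-induced repressor of the receptor, rose by 0.71 ± 0.06, 1.16 ± 0.06 and 1.5 ± 0.06. At 20 µg/mL the other largest rises were those of GUSBP11, the pro-apoptotic BMF (0.82 ± 0.09) and the inositol transporter SLC5A3. Those at 100 µg/mL were of ALDH1A3 (1.36 ± 0.06), CYP1B1-AS1 (1.3 ± 0.13) and MT-RNR1 (1.28 ± 0.13). The largest falls at 20 µg/mL, of TMEM160, BCYRN1, CDC42EP5, ROMO1 and S100A2, were not called without Banhasasim 20 replicate 2 or replicate 3, either of which leaves 1 library at that dose. Those of TMEM160, ROMO1, MT-CO2 and S100A6 at 100 µg/mL were not called without vehicle replicate 1 or either Banhasasim 100 library, nor TYMSOS without Banhasasim 100 replicate 3.

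At 500 µg/mL of Banhasasim the 10 largest rises against the vehicle were those of CYP1A1, MT-RNR1 (4.45 ± 0.14), SLC6A9 (3.42 ± 0.15), MT-RNR2 (3.21 ± 0.14), CHAC1 (2.95 ± 0.09), CYP1B1, the peptide hormone ADM2 (2.31 ± 0.15), DDIT4 (2.10 ± 0.08), ASNS (1.95 ± 0.05) and ALDH1A3 (1.82 ± 0.06). Falls included TXNIP (-1.50 ± 0.06, adjusted p = 1.59e-16), the Wnt inhibitor DKK1 (-1.21 ± 0.10), DSEL (-1.38 ± 0.11), MT-ND4 (-1.70 ± 0.19), MT-CO2, MT-CO3 and MT-CO1. Falls of TMEM160 (without Banhasasim 500 replicate 2 or 3), MT-ND3 and MT-ATP6 (without replicate 3) were lost on removing a library. ATF4 targets (20 of 22 higher and 0 lower, 21 and 0 adjusted over the list alone, camera adjusted p = 8.09e-39) and NRF2 targets (16 and 0, 17 and 0 adjusted over the list alone, 8.32e-20) were higher. MAPK output genes (7 and 1, 9 and 2 adjusted over the list alone, 0.00128) were also higher. Cholesterol synthesis (0 and 19 of 24, 0 and 19 adjusted over the list alone, 6.58e-15) and G2/M genes (0 and 13 of 22, 0 and 16 adjusted over the list alone, 1.51e-10) were lower. So were goblet cell genes (1 and 8 of 16, 2 and 10 adjusted over the list alone, 8.28e-04). MUC13 was at -0.61 ± 0.05 and KIF20A, a kinesin of cytokinesis, at -0.39 ± 0.05. Mitochondrial mRNAs were lower (0 and 8, 0 and 11 adjusted over the list alone, camera adjusted p = 1.35e-09, adjusted p = 0.121 with an estimated correlation), as was interferon response (0 and 9, 0 and 12 adjusted over the list alone, 7.98e-07, then 0.0504). In total 2870 genes were called (1533 higher and 1337 lower, 221 over 2-fold), and 1470 without Banhasasim 500 replicate 3.

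For Sayeok at 500 µg/mL against the vehicle (n = 3 each), NDRG1 (1.22 ± 0.15, edgeR adjusted p = 1.66e-05), SLC38A4 (1.14 ± 0.11), AKR1C2 (1.05 ± 0.08, adjusted p = 1.43e-08), and ALDH3A1 (0.75 ± 0.07) were among the 10 largest rises. SLC5A3, the pyruvate dehydrogenase kinase PDK4, the cholesterol exporter ABCG1 and TRIB2 were too. The differentiation-linked annexin ANXA13 changed by -0.81 ± 0.07 (from 49.04 to 27.99 CPM, adjusted p = 2.37e-08), SLC14A1 by -0.96 ± 0.09 and REG4 by -0.87 ± 0.09. DSEL, HES6, ZG16B, NUDT8 and MOGAT3 also fell. NDRG1, AKR1C2, ALDH3A1, SLC14A1 and REG4 also changed between 500 and 20 µg/mL of Sayeok, where fold changes do not use the vehicle. SLC5A3 was also higher than in the vehicle in the Yijung library at 20 µg/mL (log2 ratio 0.53, without a test). Part of the rise of SLC5A3 may therefore come from a difference of the vehicle libraries. RN7SL2, PITX1-AS1, ROMO1 and BCYRN1, also by rule among the largest changes, were not called without vehicle replicate 1, and each was also lost on removing at least 2 other libraries singly. Targets of AhR (6 and 0 of 8, 6 and 1 adjusted over the list alone, camera adjusted p = 7.04e-07) and NRF2 (16 and 0, also adjusted over the list alone, 1.9e-13) were higher. So were PXR and CAR genes (7 and 1, also adjusted over the list alone, 2e-05), PPAR targets (8 and 0, also adjusted over the list alone, 2.63e-04) and ATF4 targets (6 and 0, 8 and 0 adjusted over the list alone, 4.06e-05). Cholesterol synthesis (1 and 11, also adjusted over the list alone, 1.85e-04) and goblet cell genes (0 and 6, also adjusted over the list alone, 0.00119) were lower. These 7 lists were called with an estimated correlation as well. The 3117 genes called (1564 higher and 1553 lower, 127 over 2-fold) became 1437 without vehicle replicate 1, 1775 without Sayeok 500 replicate 2 and 1965 without Sayeok 500 replicate 3.

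For Bojungikgi at 500 µg/mL against the vehicle (n = 3 each), SLC38A4 rose by 1.31 ± 0.11 (edgeR adjusted p = 4e-08), CYP1B1 by 0.90 ± 0.04 (adjusted p = 1.04e-12). The endotoxin receptor TLR4 rose by 0.77 ± 0.09 (adjusted p = 3.86e-06), the zinc finger gene ZNF460 by 0.88 ± 0.17 and SLC5A3 by 0.72 ± 0.10. The cation transporter SLC22A3 rose by 0.66 ± 0.07, PDK4 by 0.62 ± 0.09 and LGR5, the receptor that marks intestinal stem cells, by 0.61 ± 0.06 (adjusted p = 1.48e-07). IFIT1 changed by -0.87 ± 0.11 (adjusted p = 9.6e-06). CYP1B1, SLC38A4 and IFIT1 also changed between 500 and 20 µg/mL, where fold changes do not use the vehicle. TLR4, ZNF460 and SLC5A3 were also among the largest changes at lower Bojungikgi doses. In the Yijung library at 20 µg/mL, TLR4 and SLC5A3 had log2 ratios of 0.521 and 0.53, without a test. The rises of TLR4, ZNF460 and SLC5A3 cannot therefore be told apart from a difference of the vehicle libraries. Falls of ROMO1, IFI27, S100A6, RPLP1, PDZK1IP1 and TMEM256 were called only with all groups in the fit, as were the changes of TMEM160 and UCKL1-AS1, which were also lost without both vehicle replicate 1 and Bojungikgi 500 replicate 2. That of TMEM160 was lost with the GC and length correction too. Those of RN7SL2, CEMP1 and RPS29 were not called without vehicle replicate 1, nor CEMP1 and RPS29 without Bojungikgi 500 replicate 2. AhR targets (6 and 0 of 8, 7 and 0 adjusted over the list alone, camera adjusted p = 3.52e-08) and PXR and CAR genes (6 and 1, also adjusted over the list alone, 0.00195) were higher. Cholesterol synthesis was lower (0 and 16, 0 and 17 adjusted over the list alone, 1.03e-08). These 3 lists were called with an estimated correlation as well, which others were not. NRF2 targets (10 and 3, 11 and 4 adjusted over the list alone, 0.00124) reached adjusted p = 0.0801 with an estimated correlation. Oxidative phosphorylation (1 and 17 of 23, 1 and 20 adjusted over the list alone, 5.31e-06) reached 0.24 and ribosomal proteins (0 and 23 of 28, 0 and 27 adjusted over the list alone, 6.35e-09) 0.258. Vehicle replicate 1 and Bojungikgi 500 replicate 2, both in this comparison, held the highest and lowest shares of counts on ribosomal protein genes (6.91% and 3.775%). The 5580 genes called (2688 higher and 2892 lower, 193 over 2-fold) became 2822 without vehicle replicate 1 and 3102 without Bojungikgi 500 replicate 2.

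Mitotic genes at 20 µg/mL of Banhasasim, Sayeok and Bojungikgi were lower than in the vehicle. CCNB1, the cyclin that drives entry into mitosis, was at 196 ± 7.29 CPM in the vehicle. It changed by -0.42 ± 0.06 with Banhasasim (edgeR adjusted p = 5.25e-05), -0.44 ± 0.05 with Sayeok (adjusted p = 1.05e-05) and -0.40 ± 0.05 with Bojungikgi (adjusted p = 3.02e-05). PLK1, a kinase of spindle assembly, changed by -0.45 ± 0.06, -0.46 ± 0.06 and -0.47 ± 0.06. Of 22 G2/M genes, 14, 14 and 13 were lower and 0 higher (15, 15 and 14 adjusted over the list alone, camera adjusted p = 4.17e-11, 1.66e-10 and 1.12e-09). The numbers lower at 100 µg/mL were 12, 13 and 12 (15, 14 and 12 adjusted over the list alone, 1.83e-10, 4.8e-10 and 2.78e-07). These 6 calls held with an estimated correlation, with the GC and length correction, and without both vehicle replicate 1 and Bojungikgi 500 replicate 2. With the correction and an estimated correlation together, the list was not called for Sayeok at 100 µg/mL (camera adjusted p = 0.0738). All 6 use the same vehicle libraries, so they are not independent of each other. A difference of the vehicle itself cannot be told apart from an effect shared by the extracts. From 20 to 500 µg/mL of Sayeok and Bojungikgi the list rose. Some of the largest changes were called in every setting tried. These were PTPRO (0.63 ± 0.06), GPRIN3, GUSBP11, RPLP1 and S100A2 (-0.85 ± 0.15) with Sayeok and SLC5A3, GPRIN3, TMEM265, SMIM6 and S100A2 (-0.72 ± 0.15) with Bojungikgi. The same held for ABCA1 (0.56 ± 0.09) at 100 µg/mL of Sayeok, and for TLR4 (0.55 ± 0.09) and PTPRO (0.53 ± 0.06) at 100 µg/mL of Bojungikgi. At that dose the other largest changes were lost in at least 1 setting. For Sayeok these were MAMDC4, ZNF460, PGGHG, NEIL1, RPS29, IFI6, S100A6, ROMO1 and RPLP1, and for Bojungikgi RN7SL2, ZNF460, ZNF417, TMEM265, RPLP1, ROMO1, S100A2 and S100A6. The other largest changes at 20 µg/mL of Sayeok or Bojungikgi, of ZNF460, ZBED6, FSIP2, TMEM160, RPS29, ROMO1 and S100A6, were not called without vehicle replicate 1. AKR1B10 was lower than in the vehicle at 20 µg/mL of Sayeok (-0.41 ± 0.06) and Bojungikgi (-0.35 ± 0.06).

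Ribosomal protein genes were lower as a list at 20 and 100 µg/mL of the same extracts, but every such call was lost with an estimated correlation. With Banhasasim, Sayeok and Bojungikgi at 20 µg/mL, 4, 7 and 7 of 28 were lower (5, 19 and 11 adjusted over the list alone, camera adjusted p = 1.01e-05, 4.69e-06 and 6.12e-06, then adjusted p = 0.614, 0.675 and 0.602 with an estimated correlation). At 100 µg/mL the numbers were 3, 12 and 9 (2, 21 and 15 adjusted over the list alone, camera adjusted p = 3.72e-05, 2.56e-09 and 2.78e-07, then adjusted p = 0.548, 0.356 and 0.427 with an estimated correlation). Members with small p under Bojungikgi and Sayeok at 20 µg/mL, RPLP0 and RPL7A, were not called without vehicle replicate 1.

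These counts of genes depended on vehicle replicate 1. With all libraries at 20 µg/mL, 2379 genes were called for Banhasasim (1208 higher and 1171 lower), 3555 for Sayeok (1666 and 1889) and 3440 for Bojungikgi (1712 and 1728). Without that library there were 608, 990 and 844. At 100 µg/mL, 2229 (1184 and 1045), 2636 (1215 and 1421) and 2964 (1423 and 1541) became 620, 480 and 491. Treated libraries mattered as well. For Banhasasim the count at 20 µg/mL was 393 without its replicate 2 and 329 without replicate 3, and at 100 µg/mL 1252 and 210. For Sayeok it was 1746 without Sayeok 20 replicate 3, and 972 and 1342 without Sayeok 100 replicates 2 and 3. For Bojungikgi it was 2212, 1874 and 1594 without Bojungikgi 20 replicates 1, 2 and 3, and 858 and 1401 without Bojungikgi 100 replicates 1 and 3.

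**Figure D5:**
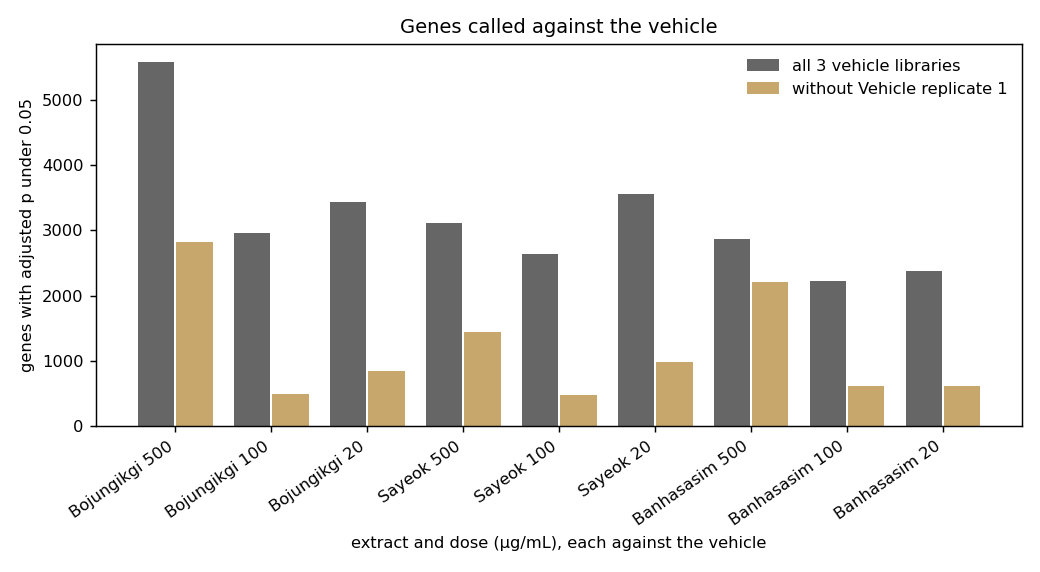
Number of genes called against the vehicle for each extract and dose, with all 3 vehicle libraries and without vehicle replicate 1. Without that library the counts at 20 µg/mL were 608 for Banhasasim, 990 for Sayeok and 844 for Bojungikgi.

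Fold changes against the shared vehicle correlated between extracts by construction, so r and covariance are given beside simulated data with no treatment effect. Overlaps of called genes were not simulated. At 20 µg/mL across genes, r was 0.946 (Bojungikgi and Sayeok), 0.923 (Bojungikgi and Banhasasim) and 0.928 (Sayeok and Banhasasim), against simulated means of 0.439 to 0.496. Covariances, of log2 ratios of group mean CPM, were 0.0393, 0.0388 and 0.0403, against highest simulated values of 0.0052 to 0.0055. The pairs shared 1315, 1012 and 1016 higher genes and 1360, 977 and 1035 lower genes, with 0, 0 and 1 in opposite directions. At 500 µg/mL, r was 0.863, 0.573 and 0.674 and the covariances were 0.0423, 0.034 and 0.0323, against simulated mean r of 0.504, 0.456 and 0.449 and highest simulated covariances of 0.0056, 0.0057 and 0.0056. There the pairs shared 1268, 801 and 750 higher genes and 1194, 742 and 699 lower genes, with 2, 46 and 11 in opposite directions.

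A direct comparison of Bojungikgi with Sayeok at 500 µg/mL (n = 3 each) asked how the formulas differ at the same dose. CYP1B1 was higher with Bojungikgi, 91.2 ± 2.19 against 63.5 ± 1.85 CPM (0.52 ± 0.04, edgeR adjusted p = 1.86e-07), and IGFL2-AS1 was lower (-0.90 ± 0.10, adjusted p = 1.62e-05). ALDH1A3 (0.43 ± 0.06) and the bicarbonate transporter SLC4A4 (0.39 ± 0.07) were called only with all groups in the fit. So were AKR1C2 (-0.65 ± 0.08), the long non-coding RNA UCA1 (-0.58 ± 0.08), DDIT4 (-0.51 ± 0.08) and the autophagy receptor SQSTM1 (-0.35 ± 0.05). Among the other largest changes, NAALADL2, DPYD and NDRG1 were not called without Sayeok 500 replicate 1, and each was also lost on removing at least 1 Bojungikgi 500 library. The test called 45 genes (15 higher and 30 lower). It called 22 without Sayeok 500 replicate 1, 29 without Sayeok 500 replicate 2, 28 without Bojungikgi 500 replicate 2 and 72 without Bojungikgi 500 replicate 3. Targets of NRF2 (0 and 3, 0 and 12 adjusted over the list alone, camera adjusted p = 9.97e-13) and ATF4 (0 and 4, 0 and 14 adjusted over the list alone, 2.19e-12) were lower with Bojungikgi. So were cholesterol synthesis (0 and 0, 0 and 9 adjusted over the list alone, 3.49e-08) and autophagy (0 and 1, 0 and 4 adjusted over the list alone, 1.42e-05). Hypoxia (0 and 2, 0 and 5 adjusted over the list alone, 1.19e-05) and NF-kB genes (0 and 0, 0 and 2 adjusted over the list alone, 0.00642) were lower too. These 6 lists were called with an estimated correlation as well.

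At 100 and 20 µg/mL, edgeR called 0 genes between Bojungikgi and Sayeok, and DESeq2 called 0 and 1. Of 18783 genes, 935 and 329 had an unadjusted p under 0.05 in edgeR. Tests without any difference would give about as many as were found at 100 µg/mL and more than at 20 µg/mL. Without the filter on low counts edgeR called 113 and 79. At 100 µg/mL 6 lists were called by camera with 0 genes called over all genes. Higher with Bojungikgi were the unfolded protein response (camera adjusted p = 0.00824), AhR targets (0.0228) and heat shock (0.0295). Fatty acid synthesis (0.0228), hypoxia and glycolysis (0.0386) and fibroblast and endothelial markers (0.0386) were lower. With an estimated correlation only the unfolded protein response was called (adjusted p = 0.0311). That call was lost with the GC and length correction (camera adjusted p = 0.295). Only AhR targets were called then (camera adjusted p = 0.0433), and not with an estimated correlation (0.248). At 20 µg/mL 0 lists were called (smallest camera adjusted p = 0.427).

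Yijung had 1 library per dose, so its values are ratios to the vehicle mean without a test. The median log2 ratio of AhR targets at 500 µg/mL was 0.38, at percentile 100 of 10000 random lists of like expression, which describes this library only. It was 0.28 for PXR and CAR genes (percentile 99.98) and 0.18 for NRF2 targets (100). For cholesterol synthesis it was -0.13 (0.08), for interferon response -0.18 (0.23) and for ATF4 targets 0.03 (73.67). TLR4 was at 18.7 CPM against 11.9 ± 1.42 in the vehicle (log2 ratio 0.65) and HES6, a neural and secretory lineage factor, at 12.6 against 22.8 ± 2.84 (-0.86). At 100 µg/mL interferon response genes were higher instead (0.28, percentile 100), with OAS2 at 0.82, IFI44 at 0.67 and MX1 at 0.66. The phosphatase PTPRO was higher at 20 µg/mL (0.59) and the mitotic ubiquitin-conjugating enzyme UBE2S lower (-0.75). G2/M genes were lower at all 3 doses, with medians of -0.14, -0.14 and -0.21 from 500 to 20 µg/mL (percentiles 0.01, 0.01 and 0). These ratios share the vehicle libraries, so the difference of the vehicle from every replicated extract may enter them. Several of the other ratios picked by rule concern readthrough genes or members of multicopy families, such as EIF3CL at 100 µg/mL (-3.55), whose reads map ambiguously.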

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

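The tests of carryover of RNA without poly(A) tails, of the share of counts on ribosomal RNA, of the splits of libraries and of the GC and length correction were chosen only after the result was seen. The change from 20 to 500 µg/mL differed between extracts, by a test of the difference itself, in 386 genes for Banhasasim against Bojungikgi and in 196 genes for Banhasasim against Sayeok. They included ATF4 and AhR targets, of which 20 of 22 and 6 of 8 rose more with Banhasasim than with Bojungikgi, and 17 and 5 more than with Sayeok. Banhasasim had 2 libraries per dose, and without Banhasasim 20 replicate 3 the counts were 186 and 116, without Banhasasim 20 replicate 2 they were 199 and 125, and without Banhasasim 500 replicate 2 they were 169 and 130. Whether the extracts reached cells at comparable active concentrations was not tested.

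The vehicle libraries differed alike from all 3 replicated extracts at 20 µg/mL, where the covariance between extracts of differences in mean log2 CPM averaged 0.041, 7.36 times the highest of 20 simulations that shared the vehicle without an effect (0.00556). Without vehicle replicate 1, 62.1% of the covariance was left, at 0.0254 or 3.11 times the highest simulated value (0.00817), narrowly past a bound of 3 set beforehand. Then 608, 990 and 844 genes were still called for Banhasasim, Sayeok and Bojungikgi. The simulations drew genes independently with a spread pooled over all groups, without trends shared across a library, so the bound may be too low. That library as the whole cause is therefore argued against only relative to these simulations. Much of the counts rested on that library all the same, as the full counts were 2379, 3555 and 3440. A bias of GC content and transcript length as the whole cause is argued against by the 65.4% left after correction, but both steps together left 45.9%, so more than 1 source may add up. With both steps the covariance of 0.0188 lay under 3 times the simulated 0.00817, though no simulation was run for corrected values. Handling or batch of the vehicle libraries cannot be told apart from an effect that the extracts share, because the vehicle has its own sample code. The titles name batch E for all libraries, though. Both extract code series differed from each other in only 4 genes at 20 µg/mL (424 at an unadjusted p under 0.05). The labels give no DMSO content for the extract libraries, so a difference in solvent could not be checked.

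In Banhasasim at 500 µg/mL, mitochondrial ribosomal RNA rose while 5 of 13 mitochondrial mRNAs were called lower than at 20 µg/mL and 0 higher, a list call that was lost with an estimated correlation (adjusted p = 0.142). A list of RNAs without poly(A) tails changed by a median of -0.138 between 500 and 20 µg/mL, with 0 of 26 measured members higher and 3 lower. It held only histone mRNAs (18 measured, at most 0.258) and small structured RNAs (8 measured, at most 0.91). Some lay near the floor, such as SCARNA2 at 0.09715 and 0.05296 CPM, and cytosolic ribosomal RNA was not on it. These values argue against carryover that raised the listed RNAs like mitochondrial ribosomal RNA, but not against carryover of other RNAs. Counts taken by both ribosomal RNA genes are argued against as the cause of the lower values. Their share lowers every other gene by a log2 change of -0.155, whereas the mRNAs' shares of all counts changed by a median of -1.088 (quartiles -1.272 and -0.749) and those of 18668 other genes by -0.13. Taking both genes out before scaling decides nothing, since it left the median of the mRNAs at -0.943 against -0.938. RNA degradation cannot be told apart from the rest, as the rank correlation of fold change with transcript length, -0.163 over 18642 genes, lay between the bounds of -0.2 and -0.1 set beforehand. A candidate explanation that stays a hypothesis is a change in the polyadenylation, processing or stability of mitochondrial transcripts under this extract, for which no test could be run on gene counts.

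For the numbers of genes called with 3 libraries per group and only those groups fitted, the 6 libraries make 10 splits, too few for a share under 0.05. The real count was the only one as large in 9 comparisons (1 split each). Against the vehicle it was 189, 187 and 1985 for Bojungikgi at 500, 100 and 20 µg/mL and 1264, 220 and 1537 for Sayeok, with a highest other count of 0 in all 6. Between 500 and 20 µg/mL it was 54 against 1 for Bojungikgi and 764 against 2 for Sayeok, and for Bojungikgi against Sayeok at 500 µg/mL it was 2 against 0. At 100 µg/mL of these extracts the real count was 0 and the highest other 5, with 10 splits as large, and at 20 µg/mL it was 1 and the highest other 3, with 7 splits as large.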

How the results depend on the processing

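The tests with the GC and length correction, with that correction and a replicate block, and without vehicle replicate 1 and Bojungikgi 500 replicate 2 together were chosen only after the result was seen. Relative log expression size factors, the replicate block and DESeq2 kept every count of called genes within 1.5 times, except that DESeq2 called 97 genes for Bojungikgi against Sayeok at 500 µg/mL (45 in edgeR) and 1 at 20 µg/mL (0 in edgeR). The replicate block changed no list call in the comparisons whose numbers pair and moved no count by more than 1.5 times. All 160 genes named for the size of their change were called under size factors, no filter, the block and DESeq2. Of them 152 were called with the GC and length correction, 154 with it and the block, 134 without both departing libraries, 107 with only the compared groups and 112 whichever single library was left out, and 0 changed direction.

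With only the compared groups in the fit, counts against the vehicle at 500, 100 and 20 µg/mL were 189, 187 and 1985 for Bojungikgi, 1264, 220 and 1537 for Sayeok and 648, 39 and 38 for Banhasasim. They were 54 for Bojungikgi 500 against 20 µg/mL and 2 and 1 for Bojungikgi against Sayeok at 500 and 20 µg/mL. By construction this fit has fewer residual degrees of freedom. That alone does not account for the falls, since the Bojungikgi fits all had 3 libraries per group but fell unequally. Their counts with all groups had been 5580, 2964 and 3440. Replicates differed by a chi-square per gene of up to 44.028, 14.618 and 7.029 at 500, 100 and 20 µg/mL of Bojungikgi. A dispersion pooled over all groups may understate the spread of the noisier ones, so their main counts may be too high. Without both departing libraries the counts were 1569, 1446 and 1866 for Bojungikgi against the vehicle, 1315 and 2043 for Sayeok at 100 and 20 µg/mL, 1355 and 1530 for Banhasasim at 100 and 20 µg/mL, 1040 for Sayeok 500 against 20 µg/mL and 2392 for Banhasasim 500 against 20 µg/mL. The last pair rose although no library of those groups was left out. The omitted libraries could act on these counts only through the dispersions, filter and scaling shared by the fit. Which of these mattered was not tested.

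With the GC and length correction the counts were 1649 and 2193 for Bojungikgi at 100 and 20 µg/mL against the vehicle, 911 for Bojungikgi and 1067 for Sayeok 500 against 20 µg/mL and 121 for Bojungikgi against Sayeok at 500 µg/mL. With the block added these were 1813, 2278, 966, 1144 and 133, and Banhasasim at 100 and 20 µg/mL gave 1423 and 1437. Without the filter on low counts there were 606 genes for Bojungikgi 500 against 20 µg/mL and 593, 113 and 79 for Bojungikgi against Sayeok at 500, 100 and 20 µg/mL. The interaction of Banhasasim with Bojungikgi gave 963 genes without the filter, 641 with the correction and 697 with the correction and block, and that with Sayeok gave 327, 388 and 398, and 332 without both departing libraries. The cause was not tested for any of these.

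Leaving out 1 library at a time, which also lowers the number of samples, gave counts against the vehicle at 500, 100 and 20 µg/mL from 2822 to 6054, 491 to 4078 and 844 to 4352 for Bojungikgi, 1437 to 3793, 480 to 3570 and 990 to 4370 for Sayeok and 1470 to 3077, 210 to 3279 and 329 to 3491 for Banhasasim. Between 500 and 20 µg/mL they ran from 164 to 354 for Bojungikgi, 386 to 445 for Sayeok and 636 to 1519 for Banhasasim. Bojungikgi against Sayeok gave 22 to 72 at 500 µg/mL and 0 at the lower doses, and the interactions gave 169 to 535 and 116 to 197.

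Of 280 list tests in the 10 comparisons of 500 or 20 µg/mL with the vehicle, of 500 with 20 µg/mL and of Bojungikgi with Sayeok at 500 µg/mL, 116 were called with the preset correlation, 64 with an estimated one, 135 with fry, 95 with the GC and length correction and 119 without both departing libraries. In the other comparisons the preset and the estimated correlation called 5 and 1 lists for Bojungikgi, 6 and 1 for Sayeok and 7 and 2 for Banhasasim at 100 µg/mL against the vehicle. They called 6 and 1 for Bojungikgi against Sayeok at 100 µg/mL, 0 and 0 at 20 µg/mL, and 8 and 3 for the interaction with Bojungikgi and 8 and 5 for that with Sayeok. For Yijung, pooling the spread of the other groups called 6 of 30 named genes, namely TLR4 and HES6 at 500, IFI44 at 100 and PTPRO, TLR4 and UBE2S at 20 µg/mL, which assumes that a lone library varies as the others do. Over all genes that fit called 338, 50 and 128 at 500, 100 and 20 µg/mL. Of 1026 pairs of a named gene and a comparison, 227 were no longer called with the correction, 177 without both departing libraries, 544 with only the compared groups and 468 in at least 1 leave-one-out fit. With the correction 9 changed direction, and the cause was not tested. Without and with the block, log2 changes became -0.079 and -0.078 for SOD2 (0.14 before), 0.003 and 0.004 for CLDN3 (-0.35) and -0.008 and -0.007 for OCLN (0.17) in Bojungikgi 500 µg/mL against vehicle. At 100 µg/mL they became -0.046 and -0.046 for NDUFS1 (0.13), -0.01 and -0.009 for PHLDA1 (0.15) and 0.014 and 0.013 for CLDN3 (-0.29), and at 20 µg/mL -0.031 and -0.031 for PHLDA1 (0.13). CLDN3 in Sayeok 20 µg/mL became 0.008 and 0.011 (-0.29), and HSPA4L in Banhasasim 100 µg/mL -0.009 and -0.001 (0.19). At this depth and replication, simulated 1.5-fold changes in genes of at least 1 CPM were recovered at 78% or more, and smaller ones were often missed.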

Other observations

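The test of position along the mitochondrial genome was chosen only after the result was seen. NRF2 and AhR targets rose from 20 to 500 µg/mL of Banhasasim, Sayeok and Bojungikgi. Interferon response and cholesterol synthesis genes fell with each of these extracts. By the interaction terms the NRF2 and AhR lists rose more with Banhasasim, though few NRF2 targets were called as rising more than with Sayeok. At 20 µg/mL of Bojungikgi the NRF2 list was lower than in the vehicle (camera adjusted p = 0.00949, then 0.429 with an estimated correlation). Part of its rise there may therefore lie below the vehicle level. Members called higher numbered 20, 19 and 12 of 24 NRF2 targets and 7, 5 and 7 of 8 AhR targets, and members called lower numbered 12, 11 and 10 of 20 interferon genes and 13, 3 and 8 of 24 cholesterol synthesis genes. The comparisons of 500 with 20 µg/mL share no library with each other, and their fold changes do not use the vehicle libraries.

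The mitochondrial mRNAs changed by different amounts between 500 and 20 µg/mL of Banhasasim, from -1.501 for MT-ND4 to 0.835 for MT-ND6, with 5 of 13 called lower and the list not called with an estimated correlation (adjusted p = 0.142). The hypothesis that the fall grows with distance from the heavy-strand promoter was tested over the 12 mRNAs of that strand, which are too few to decide it. Spearman's rho between log2 fold change and position was 0.014 (permutation p = 0.974) and Pearson's r was 0.197 (permutation p = 0.541, 100000 permutations, two-sided), and without the 2 genes farthest from the median position rho was -0.2 and r was 0.164. The genes are not independent replicates.

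No pair of replicate libraries was as close as 1 library counted again, as the chi-square per gene between replicates ran from 4.467 to 45.073, where counting error alone would give about 1. These values do not tell separate cultures from repeat libraries of the same RNA.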
